A study of Mus musculus with 24 samples.

How the data were processed

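Droplet-based 5' single-cell RNA libraries were made from 8 tumors and 8 spleens, with TCR libraries from the tumors, per the labels' protocols. Tumors were digested with enzymes, and spleens were mashed and their red cells lysed. Per the submitters' processing notes, Cell Ranger 5.0.1 on GRCm38, Seurat 4.0.4 and R 4.0 were used. The deposited matrices hold raw UMI counts per gene and barcode, with 32286 features including the SV40 transgene, and were used as whole numbers. Cell type labels were taken from the authors' deposited annotation and clones from their deposited table. Deposited merged matrices were not used here. No doublet caller was run, and barcodes without a label were left out.

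For each library and class, counts were summed over annotated cells, keeping sums of at least 10 cells. A class was the union of the authors' labels of its type. Sums were tested with edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM, robust quasi-likelihood fit and test, Benjamini-Hochberg adjustment within a contrast, threshold 0.05). All 4 groups of a tissue shared one estimate of the spread, with 4 residual degrees of freedom where all 8 libraries entered. Batch could not be a term because it is aliased with PD1-IL2v. Background genes were those with a CPM over all cells of the tissue more than 5 times that in the class. Libraries of a group differed beyond sampling noise (chi-square per degree of freedom 14.1 to 112), and all carried Y-linked transcripts. Gene coordinates were matched by gene identifier to the GRCm38 annotation.

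Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with the estimated correlation beside it and fry as an alternative, adjusted over lists, where at least 5 members were measured. List counts are of measured members. The 17 functional lists covered IFN-gamma and IFN-alpha response, MHC class I and II, immunosuppressive and inflammatory macrophage genes, effector and cytotoxic, exhaustion, IL-2 and STAT5 response, stem-like and naive-memory, regulatory T cell, proliferation, angiogenesis, endothelial recruitment, glycolysis and hypoxia, beta cell identity, and stress and immediate-early genes. The 12 marker lists covered T, NK, B, macrophage, neutrophil, dendritic, endothelial, fibroblast and pericyte, cancer, acinar and ductal, islet hormone, and erythroid and platelet genes. Members without counts in a group were set to a bound of 3 counts over the group.

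Class shares were tested with edgeR on cell numbers with total annotated cells as offset, and by exact two-sided permutation over 4 against 4 libraries (70 splits). TCR clones of 2 or more cells were counted after drawing each library to the smallest, as the mean of 1000 draws. CD3 shares were also taken with cells thinned to 1000 UMIs. The share of T cell RNA in spleen B cells was taken as their CD3 CPM over that of T cells of the same spleen, and that of NK RNA from the NK marker list.

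Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per class and contrast, up to 8 genes per direction (4 in the interaction) with the largest change past the threshold, separated libraries and a mean log2 CPM of at least 5 (4 where few reached it). It left out gene models, ribosomal, mitochondrial, receptor segment, sex-linked and background genes. It added the 3 members with the smallest p of each list past its threshold, and genes of the drug targets. The first genes of each ranking are printed. Genes with at most 3 counts in a group are given as CPM. Alternatives set at the same time were DESeq2 1.42.0, RLE scaling, no low-count filter, a replicate block, equal cell numbers, background genes left out, control tumors summed, each library left out, other share denominators and TMM for shares, and other clone definitions. Selections by CD3 UMI, the macrophage and dendritic label alone, shared TCR cells left out and PD1-IL2v against aPD-L1 were added after seeing the data.

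The tests were checked on simulated data, after their first run on the deposited counts, with 200 genes changed 2-fold or 4-fold. With the spread taken from the trend, false calls over 34 comparisons ran from 0.424% to 12.5% of calls, and with the spread gene by gene from 4.00% to 53.8%. Recovery of 2-fold changes ran from 0.677% to 47.6% with the trend spread and from 0% to 46.9% gene by gene, and of 4-fold changes from 15.8% to 94.6% and 2.03% to 88.8%. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.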

Results

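Single-cell RNA was profiled in tumors and spleens of Rip-Tag5 mice, which express SV40 T antigen from the insulin promoter and develop pancreatic neuroendocrine tumors. The mice received control treatment, an antibody against PD-L1 (aPD-L1), PD1-IL2v, an IL-2 variant fused to an antibody against PD-1, or both agents (combination) for 10 days. Each of the 4 treatment groups had 2 tumor and 2 spleen RNA libraries, and the 8 tumors also had T cell receptor (TCR) libraries. Tumor libraries held 1603 to 3349 barcodes and 8954491 to 25796528 UMIs. Spleen libraries held 1822 to 7745 barcodes and 7680832 to 20818882 UMIs. The authors' annotation named 42726 of 50881 barcodes. Barcodes without a label made up 6.58% to 9.26% of tumor libraries in batch 1 and 20.1% to 39.0% in batch 2. The corresponding spleen shares were 22.8% to 33.0% and 3.73% to 9.39%. PD1-IL2v and combination libraries formed batch 1, and control and aPD-L1 libraries batch 2, so batch and PD1-IL2v cannot be told apart. aPD-L1 against control and the combination against PD1-IL2v lie within a batch. The labels put 2 mouse labels on more than 1 treatment, and both control tumors carried the same mouse label. Which libraries share an animal is therefore open, and p-values measure only the spread between these samples. Log2 changes are given with their standard errors from edgeR, and other values as mean ± SD of the 2 libraries of a group. Libraries are named by group, tissue and replicate number.

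CD8-labelled T cells made up 5.97% ± 0.703 of annotated cells in control, 24.8% ± 2.10 in aPD-L1, 77.7% ± 1.83 in PD1-IL2v and 75.6% ± 5.53 in combination tumors. Cancer cells made up 56.1% ± 0.704 in control, 34.1% ± 9.38 in aPD-L1, 7.85% ± 2.75 in PD1-IL2v and 6.33% ± 0.0486 in combination tumors. Macrophages made up 20.5% ± 5.03 in control, 20.4% ± 0.166 in aPD-L1, 2.94% ± 1.35 in PD1-IL2v and 4.89% ± 0.336 in combination tumors. CD4 T cells made up 0.556% ± 0.163 in control, 9.46% ± 6.68 in aPD-L1, 9.55% ± 6.06 in PD1-IL2v and 9.53% ± 4.76 in combination tumors. Endothelial cells made up 6.02% ± 4.78 in control, 1.39% ± 0.750 in aPD-L1, 0.0881% ± 0.0436 in PD1-IL2v and 0.0916% ± 0.130 in combination tumors. In PD1-IL2v against control tumors edgeR called CD8 T cells (log2 3.70 ± 0.42, adjusted p = 1.3e-04) and CD4 T cells (log2 4.14 ± 0.84, adjusted p = 0.00150) higher. Cancer cells (log2 -2.84 ± 0.46, adjusted p = 6.3e-04), macrophages (log2 -2.81 ± 0.48, adjusted p = 6.3e-04), endothelial cells, fibroblasts, acinar cells and neutrophils were lower, 8 of 11 classes in all by edgeR. With TMM over class counts the cancer cell change was -0.16, that of macrophages -0.16, of fibroblasts -1.98, of acinar cells -2.55 and of neutrophils -1.54, and these calls ended. The neutrophil call was also lost at log2 -5.98 to -3.39 without either PD1-IL2v tumor or control tumor 1.

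**Figure D1:**
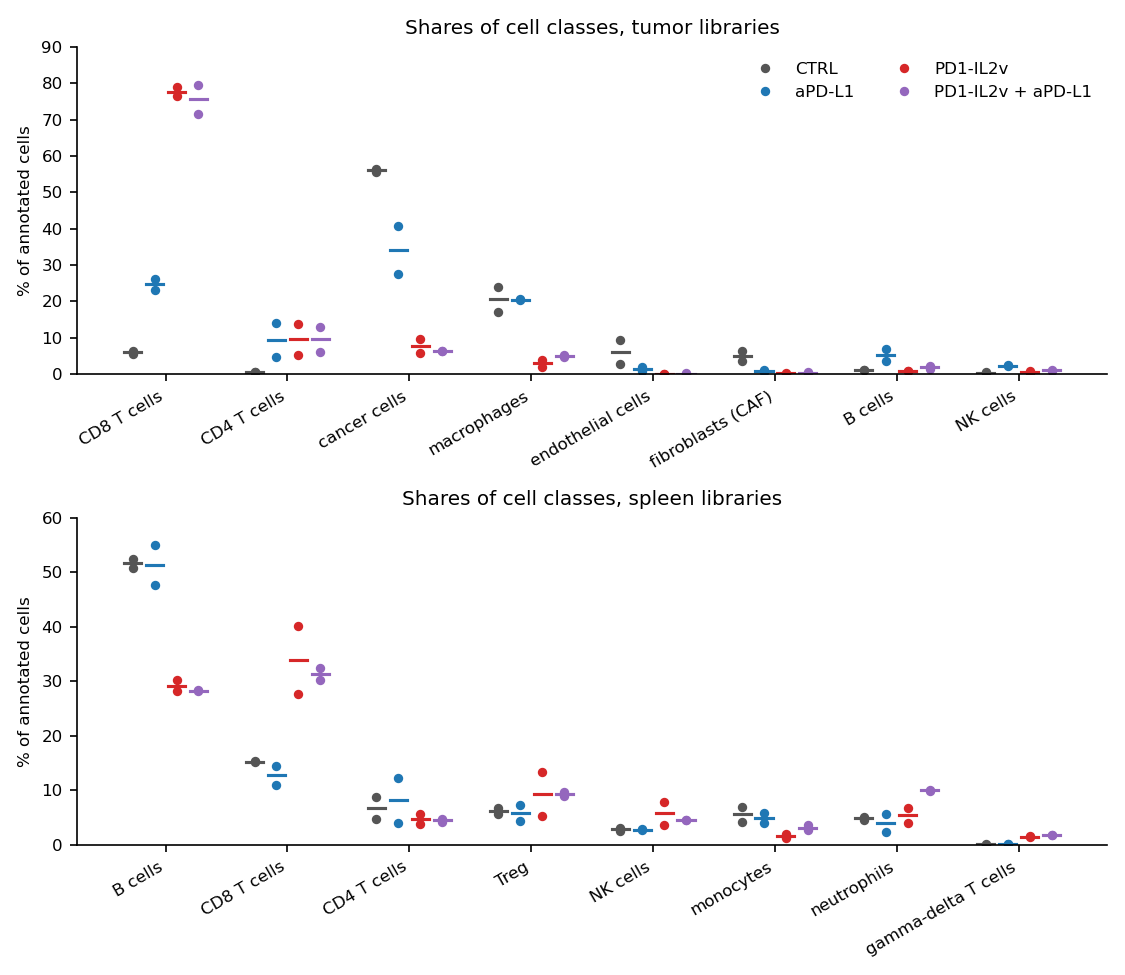
Shares of cell classes in % of annotated cells (y axis) for 8 classes of tumor libraries (upper panel) and 8 of spleen libraries (lower panel), with 1 point per library, a line at each group mean and colors for treatment. CD8-labelled T cells averaged 77.7% of cells in PD1-IL2v tumors and 5.97% in control tumors.

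Within batch 2, aPD-L1 tumors had higher shares of CD8 T cells (log2 2.05 ± 0.39, adjusted p = 0.00347), CD4 T cells (log2 4.12 ± 0.84, adjusted p = 0.00347), NK cells (log2 2.77 ± 0.59, adjusted p = 0.00347) and B cells (log2 2.15 ± 0.50, adjusted p = 0.00482) than control tumors by edgeR. Acinar cells (log2 -3.31 ± 0.70, adjusted p = 0.00347), fibroblasts (log2 -2.63 ± 0.66, adjusted p = 0.00695) and endothelial cells (log2 -2.10 ± 0.78, adjusted p = 0.0422) were lower by edgeR. The endothelial call was lost at log2 -2.10 to -0.93 without either PD1-IL2v tumor or aPD-L1 tumor 2 or control tumor 2, and with TMM over class counts (-1.75). Combination against control tumors gave 8 edgeR calls, among them CD8 T cells (log2 3.66 ± 0.42, adjusted p = 1.4e-04) and NK cells (log2 1.59 ± 0.61, adjusted p = 0.0393). The NK call was lost at log2 1.23 to 2.40 without either combination or control tumor, and among immune cells alone the NK change was -0.0153. With TMM over class counts the macrophage change of -2.07 turned to 0.35. Combination and PD1-IL2v tumors differed in 0 classes by edgeR, with 0 at an unadjusted p under 0.05. The aPD-L1 effect differed with and without PD1-IL2v for CD4 T cells (log2 -4.13 ± 1.07, adjusted p = 0.0236), CD8 T cells (log2 -2.09 ± 0.54, adjusted p = 0.0236) and fibroblasts (log2 3.49 ± 1.11, adjusted p = 0.0464) by edgeR. These calls were lost at log2 -4.41 to -3.14 without either control tumor or PD1-IL2v tumor 1 or aPD-L1 tumor 2 (CD4), log2 -2.22 to -1.98 without either combination or control tumor or PD1-IL2v tumor 1 or aPD-L1 tumor 2 (CD8) and log2 2.02 to 3.84 without either PD1-IL2v or control tumor or combination tumor 1 or aPD-L1 tumor 2 (fibroblasts). Over 4 libraries given PD1-IL2v against 4 not given it, the exact two-sided permutation test reached its smallest p of 0.0286 for CD8 T cells, cancer cells, macrophages, endothelial cells and acinar cells (adjusted 0.0629); 2 against 2 libraries cannot go below 0.333.

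Tumor macrophages were compared under aPD-L1 within batch 2. The largest rises over control were those of the protein-coding microRNA host gene AA467197 (5.18 ± 0.74), the Sca-1 antigen gene Ly6a (4.44 ± 0.75) and the complement factor B gene Cfb (4.10 ± 0.64). The largest falls were those of the Fc receptor-like gene Fcrls (-5.67 ± 0.43), the neutrophil chemokine Cxcl1 (-5.11 ± 0.38) and the pancreatic colipase gene Clps (-5.10 ± 0.52). List members that changed were H2-DMb2 (3.12 ± 0.26), H2-Ab1 (2.18 ± 0.19), H2-Eb1 (1.97 ± 0.18), the peptide transporter subunit Tap1 (1.92 ± 0.19), the MHC class II transactivator Ciita (2.29 ± 0.27), Igtp (1.72 ± 0.21), the macrophage lipid receptor Trem2 (-2.46 ± 0.16), the mannose receptor Mrc1 (-2.26 ± 0.23) and the selenoprotein P gene Selenop (-1.70 ± 0.19). Of 10 MHC class II genes, 10 rose (10 higher adjusted over the list alone; median log2 2.07). These 10 were higher by camera (adjusted p = 8.6e-15, adjusted p = 0.0613 with an estimated correlation). Of 22 IFN-gamma response genes, 16 rose (21 higher adjusted over the list alone; median log2 1.90). By camera these 22 were higher (adjusted p = 1.2e-19, adjusted p = 0.0769 with an estimated correlation). Of 21 immunosuppressive macrophage genes, 11 fell (12 lower adjusted over the list alone; median log2 -1.70). Camera on these 21 was lower (adjusted p = 6.3e-09, adjusted p = 0.0661 with an estimated correlation). Of 14 inflammatory macrophage genes, 2 rose and 1 fell (3 higher and 1 lower adjusted over the list alone; median log2 0.51, 1 background gene). These 14 were higher by camera (adjusted p = 0.0104, adjusted p = 0.0917 with an estimated correlation). Other cell types' RNA moved as well, and falls of Clps, Ctrb1 and Cela2a here and below may be RNA of acinar cells, whose share fell. Of 9 T cell marker genes, 7 rose (8 higher and 1 lower adjusted over the list alone; median log2 7.47, or 6.33 with 5 lacking counts in a group at their bound, 8 background genes). By camera these 9 were higher (adjusted p = 4.0e-12, adjusted p = 0.0820 with an estimated correlation). Of 11 acinar and ductal marker genes, 9 fell (11 lower adjusted over the list alone; median log2 -4.89, 4 background genes). Camera on these 11 was lower (adjusted p = 1.3e-14, adjusted p = 0.0917 with an estimated correlation). Of 8 dendritic cell marker genes, 5 rose (6 higher adjusted over the list alone; median log2 2.49). These 8 were higher by camera (adjusted p = 4.2e-05, adjusted p = 0.0769 with an estimated correlation). EdgeR called 670 of 8661 genes (362 higher, 308 lower), the named genes at an adjusted p of at most 0.0329. The count of 670 became 444 without aPD-L1 tumor 1, 302 without aPD-L1 tumor 2, 345 without control tumor 2, 137 with equal cell numbers and 379 with control tumors summed. Calls ended for Ly6a (log2 4.07 to 4.98) without either combination, aPD-L1 or control tumor, Cfb (log2 3.67 to 4.12) without either PD1-IL2v tumor or control tumor 2. AA467197 (ENSMUSG00000033213) lies at 122636986 to 122641191 on chromosome 2 (plus strand) and H2-Ab1 (ENSMUSG00000073421) lies at 34257689 to 34269419 on chromosome 17 (plus strand) in GRCm38.

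**Figure D2:**
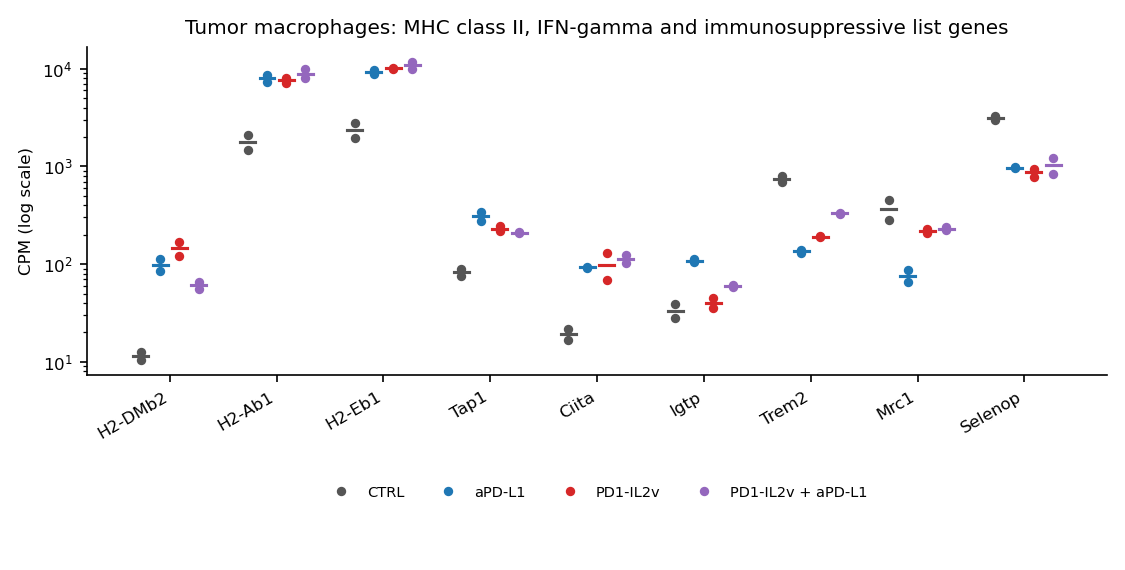
CPM (y axis, log scale) of 9 genes in tumor macrophages summed per library, with 1 point per library, a line at each group mean and colors for treatment. H2-Ab1 averaged 1773 CPM in control and 8014 CPM in aPD-L1 tumors, and Trem2 742 and 135 CPM.

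Tumor endothelial fits used 4 libraries (54 and 98 cells in control, 28 and 15 in aPD-L1). Here aPD-L1 raised the IFN-gamma-induced chemokine Cxcl9 (7.03 ± 0.53), the serine protease inhibitor Serpina3g (0.504 ± 0.713 in control and 116 ± 40.3 CPM in aPD-L1) and Cfb (5.21 ± 0.54). It lowered the chymotrypsinogen gene Ctrb1 (266 ± 100 in control and 2.09 ± 2.96 CPM in aPD-L1), Klf9 (-2.72 ± 0.45) and Depp1 (-2.0 ± 0.37). List members called were Igtp (3.12 ± 0.44), Irgm1 (1.96 ± 0.33), H2-Eb1 (4.51 ± 0.55), H2-DMb1 (3.62 ± 0.41) and H2-DMa (3.38 ± 0.44). Of 21 IFN-gamma response genes, 5 rose (18 higher adjusted over the list alone; median log2 1.96). By camera these 21 were higher (adjusted p = 4.0e-21, adjusted p = 0.206 with an estimated correlation). Of 7 endothelial recruitment genes, 1 rose (1 higher adjusted over the list alone; median log2 0.88). Camera on these 7 was higher (adjusted p = 6.5e-05, adjusted p = 0.206 with an estimated correlation). Of 18 angiogenesis genes, 0 passed the edgeR test (1 higher and 1 lower adjusted over the list alone; median log2 0.11). These 18 leaned higher without passing camera (adjusted p = 0.707, adjusted p = 0.872 with an estimated correlation). Of 10 endothelial marker genes, 0 passed the edgeR test (0 higher adjusted over the list alone; median log2 0.07). The set leaned higher without passing camera (adjusted p = 0.295, adjusted p = 0.749 with an estimated correlation). Of 6 acinar and ductal marker genes, 1 fell (5 lower adjusted over the list alone; median log2 -7.78, or -3.38 with 4 lacking counts in a group at their bound, 2 background genes). Camera on these 6 was lower (adjusted p = 4.7e-14, adjusted p = 0.206 with an estimated correlation). EdgeR called 31 of 5297 genes (27 higher, 4 lower; DESeq2 52), the named genes at an adjusted p of at most 0.0435. The count of 31 became 18 without aPD-L1 tumor 1, 51 without aPD-L1 tumor 2, 110 without control tumor 1, 86 without control tumor 2 and 89 with control tumors summed. Lost calls were those of Cxcl9 (log2 6.93 to 7.08), Depp1 (log2 -2.69 to -1.66) and H2-Eb1 (log2 3.96 to 4.89) without either aPD-L1 tumor, Serpina3g (edgeR adjusted p = 0.104), Cfb (log2 5.42), Ctrb1 (edgeR adjusted p = 0.147), Klf9 (log2 -3.51) and Irgm1 (log2 2.23) without aPD-L1 tumor 1. Cxcl9 (ENSMUSG00000029417) lies at 92321347 to 92328079 on chromosome 5 (minus strand) in GRCm38.

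Cancer cells of aPD-L1 tumors had higher levels of the near-identical interferon-induced GTPase copies, between which the split of reads is uncertain, Tgtp1 (6.02 ± 0.79), Tgtp2 (5.98 ± 0.75) and the guanylate-binding protein Gbp2 (4.79 ± 0.56) than those of control tumors. Of 23 IFN-gamma response genes, 7 rose (23 higher adjusted over the list alone; median log2 3.47, 2 background genes). These 23 were higher by camera (adjusted p = 2.1e-46, adjusted p = 0.0744 with an estimated correlation). Of 15 MHC class I genes, 5 rose (15 higher adjusted over the list alone; median log2 2.33). By camera these 15 were higher (adjusted p = 1.5e-35, adjusted p = 0.0762 with an estimated correlation). Of 19 stress and immediate-early genes, 0 passed the edgeR test (11 higher adjusted over the list alone; median log2 0.81). Camera on these 19 was higher (adjusted p = 1.6e-10, adjusted p = 0.0830 with an estimated correlation). Of 9 T cell marker genes, 0 passed the edgeR test (8 higher adjusted over the list alone; median log2 3.94, 9 background genes). These 9 were higher by camera (adjusted p = 4.1e-10, adjusted p = 0.134 with an estimated correlation). EdgeR called 23 of 13497 genes (21 higher, 2 lower; DESeq2 256), the named genes at an adjusted p of at most 0.0413. The count of 23 became 0 without either PD1-IL2v tumor, 170 without aPD-L1 tumor 1, 2 without aPD-L1 tumor 2, 3 without control tumor 1, 65 without control tumor 2 and 0 with control tumors summed. Calls were lost for Tgtp1 (log2 5.10 to 6.03) without either PD1-IL2v or combination tumor or aPD-L1 tumor 2 or control tumor 1, Tgtp2 (log2 5.49 to 6.5) and Gbp2 (log2 4.28 to 5.43) without either PD1-IL2v or control tumor or aPD-L1 tumor 2.

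Against control, macrophages of PD1-IL2v tumors had higher levels of the leukocyte adhesion molecule Jaml (5.04 ± 0.48), the IL-1 decoy receptor Il1r2 (5.03 ± 0.91) and AA467197 (4.91 ± 0.83). The sub-label Macrophage/cDC held 78.0% and 76.5% of the class in PD1-IL2v and 39.4% and 62.7% in control tumors. The largest falls were in the pancreatic elastase gene Cela2a (189 ± 131 in control and 0.689 ± 0.974 CPM in PD1-IL2v), Clps (172 ± 61.6 in control and 1.61 ± 0.334 CPM in PD1-IL2v) and Gal3st4 (105 ± 5.37 in control and 1.38 ± 1.95 CPM in PD1-IL2v). Members of the MHC class II and immunosuppressive lists that changed were H2-DMb2 (3.66 ± 0.27), H2-Eb1 (2.09 ± 0.18), H2-Ab1 (2.10 ± 0.19), Trem2 (-1.96 ± 0.17), Selenop (-1.86 ± 0.19) and Stab1 (-2.04 ± 0.25). Of 10 MHC class II genes, 10 rose (10 higher adjusted over the list alone; median log2 2.09). By camera these 10 were higher (adjusted p = 1.8e-09, adjusted p = 0.105 with an estimated correlation). Of 21 immunosuppressive macrophage genes, 1 rose and 9 fell (1 higher and 13 lower adjusted over the list alone; median log2 -1.21). Camera on these 21 was lower (adjusted p = 5.0e-04, adjusted p = 0.143 with an estimated correlation). Of 23 IFN-alpha response genes, 6 fell (9 lower adjusted over the list alone; median log2 -0.74). These 23 were lower by camera (adjusted p = 5.2e-05, adjusted p = 0.397 with an estimated correlation). Of 15 glycolysis and hypoxia genes, 5 rose and 1 fell (5 higher and 1 lower adjusted over the list alone; median log2 0.36). By camera these 15 were higher (adjusted p = 0.0326, adjusted p = 0.416 with an estimated correlation). Of 19 stress and immediate-early genes, 11 rose and 1 fell (15 higher and 1 lower adjusted over the list alone; median log2 1.00). Camera on these 19 was higher (adjusted p = 5.2e-07, adjusted p = 0.105 with an estimated correlation). Of 10 macrophage marker genes, 8 fell (9 lower adjusted over the list alone; median log2 -1.13). These 10 were lower by camera (adjusted p = 1.9e-06, adjusted p = 0.143 with an estimated correlation). Of 9 T cell marker genes, 8 rose (8 higher and 1 lower adjusted over the list alone; median log2 8.97, or 7.32 with 5 lacking counts in a group at their bound, 8 background genes). By camera these 9 were higher (adjusted p = 2.9e-08, adjusted p = 0.143 with an estimated correlation). Of 11 acinar and ductal marker genes, 9 fell (11 lower adjusted over the list alone; median log2 -6.64, or -5.61 with 3 lacking counts in a group at their bound, 4 background genes). Camera on these 11 was lower (adjusted p = 5.8e-10, adjusted p = 0.143 with an estimated correlation). EdgeR called 1506 of 8661 genes (880 higher, 626 lower), the named genes at an adjusted p of at most 0.0182. The count of 1506 became 773 without PD1-IL2v tumor 1, 975 without PD1-IL2v tumor 2, 948 without control tumor 1 and 646 with equal cell numbers. Calls ended for Il1r2 (log2 4.05 to 5.06) without either PD1-IL2v or aPD-L1 tumor or control tumor 1, Cela2a (edgeR adjusted p = 0.122 to 0.129) without either PD1-IL2v tumor.

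Cancer cells of PD1-IL2v tumors had higher levels of the interferon-induced GTPase Iigp1 (7.98 ± 1.31), Emp3 (7.46 ± 0.98) and Gbp4 (7.40 ± 0.98) than control cancer cells. Smaller falls were called for the neuronal calcium sensor Hpca (-1.5 ± 0.34), Fam57b (-1.48 ± 0.35) and the cell adhesion molecule Cadm1 (-1.30 ± 0.28). Of 23 IFN-gamma response genes, 20 rose (21 higher adjusted over the list alone; median log2 3.31, 2 background genes). These 23 were higher by camera (adjusted p = 8.3e-17, adjusted p = 0.0944 with an estimated correlation). Of 30 proliferation genes, 0 passed the edgeR test (0 higher adjusted over the list alone; median log2 0.41). By camera these 30 were higher (adjusted p = 0.0278, adjusted p = 0.704 with an estimated correlation). Of 22 beta cell identity genes, 1 rose (0 higher adjusted over the list alone; median log2 -0.12). The set leaned lower without passing camera (adjusted p = 0.274, adjusted p = 0.397 with an estimated correlation). Of 19 stress and immediate-early genes, 9 rose (11 higher adjusted over the list alone; median log2 1.05). These 19 were higher by camera (adjusted p = 1.5e-08, adjusted p = 0.0944 with an estimated correlation). Of 9 T cell marker genes, 9 rose (9 higher adjusted over the list alone; median log2 9.60, 9 background genes). By camera these 9 were higher (adjusted p = 4.0e-12, adjusted p = 0.0944 with an estimated correlation). EdgeR called 955 of 13497 genes (892 higher, 63 lower), of which 545 higher genes met the background definition, and the named genes had an adjusted p of at most 0.0378. The count of 955 became 543 without PD1-IL2v tumor 2. Lost calls were those of Iigp1 (log2 7.26 to 8.87) without either control tumor, Hpca (log2 -1.92 to -1.11) without either PD1-IL2v tumor or combination tumor 2 or aPD-L1 tumor 1 or control tumor 1, Fam57b (log2 -1.55 to -1.11) without either combination or aPD-L1 tumor or PD1-IL2v tumor 2 or control tumor 1, Cadm1 (log2 -1.39 to -0.91) without either PD1-IL2v or combination tumor or control tumor 1. The count was 221 without background genes and 56 in cancer-labelled cells without a CD3 UMI, a selection chosen after seeing the data. It left 468016 and 1144214 of 1453405 and 2749840 UMIs in the PD1-IL2v tumors, and calls ended for Iigp1 (8.51 ± 1.36), Emp3 (2.07 ± 1.05), Gbp4 (7.98 ± 1.22), Hpca (-1.22 ± 0.39), Fam57b (-1.34 ± 0.33) and Cadm1 (-1.11 ± 0.31). There the IFN-gamma list was higher (camera adjusted p = 1.6e-28, adjusted p = 0.0704 with an estimated correlation), the proliferation list lower (camera adjusted p = 1.7e-06, adjusted p = 0.365 with an estimated correlation) and the beta cell identity list higher (camera adjusted p = 0.0451, adjusted p = 0.253 with an estimated correlation).

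CD8-labelled cells with at least 1 Cd3d, Cd3e or Cd3g UMI made up 16.7% and 49.1% of the class in the 2 control tumors, 83.8% and 91.9% in aPD-L1 tumors and 99.3% and 99.0% in PD1-IL2v tumors. The single agents were therefore compared, a choice made after seeing the data, across batches. PD1-IL2v over aPD-L1 raised the interferon-induced membrane protein Ifitm1 (9.87 ± 0.66), the near-identical inducible heat shock copies, between which the split of reads is uncertain, Hspa1b (5.37 ± 0.74) and Hspa1a (5.34 ± 0.51) in CD8 T cells. It lowered the proenkephalin gene Penk (-4.73 ± 0.65), Nrn1 (-3.06 ± 0.44) and Ly6c2 (-2.86 ± 0.44). List members that changed were Nr4a3 (2.98 ± 0.28), Nr4a1 (2.20 ± 0.26), Cd244a (1.53 ± 0.37), Socs2 (2.72 ± 0.32), Nfil3 (2.28 ± 0.35) and Pim1 (1.37 ± 0.26). Of 22 IFN-alpha response genes, 13 fell (16 lower adjusted over the list alone; median log2 -1.34, 1 background gene). Camera on these 22 was lower (adjusted p = 3.5e-09, adjusted p = 0.560 with an estimated correlation). Of 19 stress and immediate-early genes, 8 rose (12 higher adjusted over the list alone; median log2 1.10). These 19 were higher by camera (adjusted p = 3.9e-08, adjusted p = 0.560 with an estimated correlation). Of 16 exhaustion genes, 5 rose (6 higher adjusted over the list alone; median log2 0.63). By camera these 16 were higher (adjusted p = 0.0177, adjusted p = 0.560 with an estimated correlation). Of 20 IL-2 and STAT5 response genes, 6 rose and 1 fell (8 higher and 2 lower adjusted over the list alone; median log2 0.82). Camera on these 20 was higher (adjusted p = 0.0219, adjusted p = 0.560 with an estimated correlation). Of 15 stem-like and naive-memory genes, 3 fell (3 lower adjusted over the list alone; median log2 -0.02). These 15 leaned lower without passing camera (adjusted p = 0.386, adjusted p = 0.846 with an estimated correlation). Of 10 cancer cell marker genes, 6 fell (9 lower adjusted over the list alone; median log2 -2.30, 10 background genes). By camera these 10 were lower (adjusted p = 6.9e-07, adjusted p = 0.560 with an estimated correlation). EdgeR called 1463 of 11736 genes (830 higher, 633 lower), the named genes at an adjusted p of at most 0.0277. The authors' sub-label Cd8_TEx held 669 of 1929 and 611 of 1380 cells of the class in PD1-IL2v and 40 of 339 and 105 of 457 in aPD-L1 tumors, and Cd8_Naive 3.53% and 4.42% against 29.8% and 30.4%. In cells with a CD3 UMI the IL-2 and STAT5 list did not pass (camera adjusted p = 0.0773, adjusted p = 0.390 with an estimated correlation) and the stem-like list was lower (camera adjusted p = 0.0484, adjusted p = 0.390 with an estimated correlation). The count of 1463 became 240 without PD1-IL2v tumor 1, 920 without PD1-IL2v tumor 2, 796 without combination tumor 1, 787 without combination tumor 2, 387 without aPD-L1 tumor 1, 187 without aPD-L1 tumor 2, 2725 without control tumor 1, 2770 without control tumor 2, 132 with equal cell numbers and 2792 with control tumors summed. Calls were lost for Penk (log2 -4.36) and Nrn1 (log2 -2.95) without PD1-IL2v tumor 1, Cd244a (log2 1.25 to 2.05) without either PD1-IL2v or aPD-L1 tumor, Pim1 (log2 1.12 to 1.41) without either aPD-L1 tumor or PD1-IL2v tumor 1. Ifitm1 (ENSMUSG00000025491) lies at 140967221 to 140969825 on chromosome 7 (plus strand) in GRCm38.

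Against control tumors, whose CD8 label held many cells without CD3 and 78.0% and 59.6% under the sub-label Cd8_Naive, PD1-IL2v raised Ifitm1 (2.83 ± 4.01 in control and 3618 ± 10.00 CPM in PD1-IL2v), the osteopontin gene Spp1 (0 ± 0 in control and 24.8 ± 10.9 CPM in PD1-IL2v) and the costimulatory receptor OX40 gene Tnfrsf4 (0.945 ± 1.34 in control and 94.2 ± 7.26 CPM in PD1-IL2v) and lowered Pgp (-2.59 ± 0.55), Ifit3 (-2.42 ± 0.39) and Fkbp2 (-2.38 ± 0.47). Of 20 effector and cytotoxic genes, 13 rose (14 higher and 1 lower adjusted over the list alone; median log2 2.16, or 2.07 with 1 lacking counts in a group at their bound). Camera on these 20 was higher (adjusted p = 5.2e-05, adjusted p = 0.197 with an estimated correlation). Of 10 cancer cell marker genes, 10 fell (10 lower adjusted over the list alone; median log2 -5.29, 10 background genes). These 10 were lower by camera (adjusted p = 8.5e-08, adjusted p = 0.220 with an estimated correlation). EdgeR called 3429 of 11736 genes (1705 higher, 1724 lower), 1075 of the lower ones by the background definition. In cells with a CD3 UMI the count was 437, the effector list (camera adjusted p = 0.110) and the cancer marker list (camera adjusted p = 0.165) did not pass. With 73835 and 127088 UMIs left in the control tumors, calls ended for Spp1 (edgeR adjusted p = 0.408), Tnfrsf4 (edgeR adjusted p = 0.0883), Pgp (-0.83 ± 0.47) and Fkbp2 (-1.44 ± 0.59). The count of 3429 became 2036 without PD1-IL2v tumor 1, 916 without control tumor 1 and 501 with equal cell numbers. Calls ended for Spp1 (edgeR adjusted p = 0.0820 to 0.394) without either control tumor, Tnfrsf4 (edgeR adjusted p = 0.117), Pgp (log2 -0.82), Ifit3 (log2 -1.34) and Fkbp2 (log2 -1.66) without control tumor 1. For aPD-L1 against control the count was 881 (362 higher, 519 lower), 8 in cells with a CD3 UMI, and 449 without PD1-IL2v tumor 1, 457 without PD1-IL2v tumor 2, 350 without combination tumor 1, 353 without combination tumor 2, 79 without aPD-L1 tumor 1, 26 without aPD-L1 tumor 2, 27 without control tumor 1, 2781 without control tumor 2, 44 with equal cell numbers and 2190 with control tumors summed. Combination against control gave 3216 genes (1588 higher, 1628 lower), 314 in cells with a CD3 UMI, and 1588 without combination tumor 1, 1963 without combination tumor 2, 757 without control tumor 1 and 434 with equal cell numbers. RLE scaling moved the median of all genes by -0.147 (log2) in PD1-IL2v against control.

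Tumor CD4 T cells, under 10 in control tumors, were compared between the single agents, a comparison chosen after seeing the data. The sub-label Treg held 2.01% and 9.78% of the class in PD1-IL2v and 23.2% and 28.7% in aPD-L1 tumors. PD1-IL2v over aPD-L1 gave higher Atf3 (5.55 ± 0.84), Hspa1a (4.51 ± 0.28) and Sv2c (5.04 ± 5.70 in aPD-L1 and 53.0 ± 10.1 CPM in PD1-IL2v). Lower genes were led by Ifit3 (-5.40 ± 0.91), Rln3 (-4.85 ± 0.51) and Ifit1 (-4.51 ± 0.51). Of 18 IFN-alpha response genes, 13 fell (16 lower adjusted over the list alone; median log2 -1.72). By camera these 18 were lower (adjusted p = 2.2e-12, adjusted p = 0.324 with an estimated correlation). Of 16 effector and cytotoxic genes, 6 rose (6 higher and 1 lower adjusted over the list alone; median log2 1.01). Camera on these 16 was higher (adjusted p = 7.6e-04, adjusted p = 0.272 with an estimated correlation). Of 14 regulatory T cell genes, 2 rose (2 higher and 1 lower adjusted over the list alone; median log2 0.08). These 14 leaned higher without passing camera (adjusted p = 0.506, adjusted p = 0.811 with an estimated correlation). EdgeR called 726 of 6974 genes (463 higher, 263 lower; DESeq2 290), the named genes at an adjusted p of at most 0.00939. The count of 726 became 404 without PD1-IL2v tumor 1, 274 without aPD-L1 tumor 2 and 322 with equal cell numbers. Lost calls were those of Atf3 (log2 9.77) and Sv2c (edgeR adjusted p = 0.0595) without aPD-L1 tumor 2.

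Whether aPD-L1 acted alike with and without PD1-IL2v was asked by the interaction, from which an additive batch effect cancels. It is the log2 aPD-L1 change with PD1-IL2v minus that without. In macrophages it was positive for Cxcl1 (8.0 ± 0.51), Cbr2 (5.57 ± 0.88) and Pmp22 (5.07 ± 0.47). It was negative for AA467197 (-5.21 ± 0.99), H2-DMb2 (-4.37 ± 0.36) and Ifi205 (-4.15 ± 0.41). Of 10 MHC class II genes, 9 had a negative interaction (10 lower adjusted over the list alone; median log2 -1.91). By camera these 10 were lower (adjusted p = 2.9e-11, adjusted p = 0.0971 with an estimated correlation). Of 21 immunosuppressive macrophage genes, 8 had a positive interaction (12 higher adjusted over the list alone; median log2 2.17, or 2.03 with 3 lacking counts in a group left out). Camera on these 21 was higher (adjusted p = 6.0e-10, adjusted p = 0.0971 with an estimated correlation). Of 9 T cell marker genes, 4 had a negative interaction (8 lower adjusted over the list alone; median log2 -8.09, or -5.95 with 5 lacking counts in a group left out, 8 background genes). These 9 were lower by camera (adjusted p = 1.3e-08, adjusted p = 0.128 with an estimated correlation). EdgeR called 301 of 8661 genes (136 higher, 165 lower), the named genes at an adjusted p of at most 0.0316. The count of 301 became 199 without PD1-IL2v tumor 1, 159 without combination tumor 1, 200 without combination tumor 2, 192 without aPD-L1 tumor 2, 187 without control tumor 2 and 65 with equal cell numbers. Calls were lost for Cbr2 (log2 4.95 to 6.74) without either PD1-IL2v or combination tumor, AA467197 (log2 -5.54 to -4.60) without either combination tumor or PD1-IL2v tumor 1 or control tumor 2.

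Adding aPD-L1 to PD1-IL2v gave few edgeR calls within batch 1, and genes named for these small counts were chosen after their values were seen. In simulations of this comparison, 16.1% or 13.5% of 2-fold changes were recovered in macrophages, 29.1% or 26.4% in CD4 T cells, 21.9% or 11.4% in CD8 T cells and 4.81% or 0.687% in cancer cells, with the spread from the trend or gene by gene. Tumor macrophages had 2 edgeR calls, Slc40a1 (2.36) and Cxcl1 (2.89) (602 at an unadjusted p under 0.05, 18 by DESeq2). Tumor CD4 T cells had Lmo4 (3.13), Calca (2.10), Trav14-3 (7.53) and Supt3 (2.22) (276 unadjusted, 0 by DESeq2). Tumor CD8 T cells had Trbv13-3 (-3.03) (225 unadjusted, 5 by DESeq2) and, in the interaction, Igfbp7 (4.77, background) and Trbv13-3 (-4.08) (1940 unadjusted, 250 by DESeq2). Under RLE the interaction had 1 gene, and the share of higher calls moved from 50.0% to 100%. Cancer cells had 0 edgeR calls (700 unadjusted, 7 by DESeq2), and 0 in the interaction (684 unadjusted, 81 by DESeq2). Counts for macrophages became 1 without PD1-IL2v tumor 1 or combination tumor 1, 0 without PD1-IL2v tumor 2, 4 without either aPD-L1 tumor and 1 with equal cell numbers. Counts for CD4 T cells became 7 without PD1-IL2v tumor 1, 91 without PD1-IL2v tumor 2, 25 without combination tumor 1, 9 without aPD-L1 tumor 1 and 1 with equal cell numbers. Counts for CD8 T cells became 0 without PD1-IL2v tumor 1 or combination tumor 1, 2 without either aPD-L1 tumor or combination tumor 2, 3 without either control tumor, 0 with equal cell numbers and 3 with control tumors summed. Counts for the CD8 interaction became 1 without either PD1-IL2v tumor or combination tumor 1, 4 without aPD-L1 tumor 2 or control tumor 1, 1673 without control tumor 2, 0 with equal cell numbers and 1001 with control tumors summed. Counts for cancer cells became 1 without PD1-IL2v tumor 1. Counts for the cancer cell interaction became 2 without aPD-L1 tumor 1 and 1 without control tumor 2. In macrophages of combination against PD1-IL2v tumors, of 29 proliferation genes, 0 passed the edgeR test (1 lower adjusted over the list alone; median log2 -1.16, 3 background genes). By camera these 29 were lower (adjusted p = 4.1e-07, adjusted p = 0.685 with an estimated correlation).

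The combination against control raised AA467197 (4.88 ± 0.81) and Jaml (4.87 ± 0.48) in macrophages and lowered Fcrls (356 ± 153 in control and 2.06 ± 1.05 CPM in combination) and Clps (-5.63 ± 0.67). Of 21 immunosuppressive macrophage genes, 1 rose and 5 fell (1 higher and 7 lower adjusted over the list alone; median log2 -0.65, mean 0.15, the signs of median, mean and test differing). The set leaned lower without passing camera (adjusted p = 0.111, adjusted p = 0.371 with an estimated correlation). EdgeR called 1186 of 8661 macrophage genes (785 higher, 401 lower). The count of 1186 became 787 without combination tumor 1, 516 without combination tumor 2, 543 without control tumor 1, 397 with equal cell numbers and 698 with control tumors summed. Calls ended for AA467197 (log2 4.61) without combination tumor 2. In cancer cells it raised Emp3 (8.26 ± 1.00) and Iigp1 (8.14 ± 1.32) and lowered Slc38a5 (-4.04 ± 0.90) and the retinol-binding protein Rbp4 (-3.41 ± 0.38). The cancer cell count was 1353 (1151 higher, 202 lower), 512 without background genes and 111 in cells without a CD3 UMI, where 292586 and 337813 UMIs were left in combination tumors and calls ended for Emp3 (2.58 ± 1.19) and Slc38a5 (-3.43 ± 0.90). The count of 1353 became 882 without combination tumor 1 and 608 without combination tumor 2. Lost calls were those of Iigp1 (log2 7.42 to 9.03) without either control tumor, Slc38a5 (log2 -4.28 to -2.16) without either combination or aPD-L1 tumor or control tumor 1. Of 9 T cell marker genes, 9 rose (9 higher adjusted over the list alone; median log2 10.21, 9 background genes). These 9 were higher by camera (adjusted p = 1.1e-10, adjusted p = 0.104 with an estimated correlation).

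Genes of the drug targets are given as mean CPM in control, aPD-L1, PD1-IL2v and combination libraries, in that order. In tumor CD8-labelled cells PD-1 and its ligands measured Pdcd1 102 ± 125, 443 ± 42.1, 1054 ± 203 and 1021 ± 196, Cd274 10.8 ± 0.762, 23.8 ± 0.664, 51.4 ± 8.58 and 47.0 ± 1.31 and Pdcd1lg2 4.45 ± 0.955, 27.6 ± 0.277, 25.8 ± 11.3 and 29.1 ± 5.25. IL-2 receptor chains there measured Il2ra 0.945 ± 1.34, 16.4 ± 2.05, 38.0 ± 1.41 and 26.8 ± 5.65, Il2rb 105 ± 84.0, 517 ± 105, 820 ± 17.3 and 767 ± 41.3 and Il2rg 180 ± 102, 554 ± 13.2, 733 ± 17.4 and 709 ± 51.3. Macrophages gave Pdcd1 0.359 ± 0.508, 44.7 ± 26.9, 65.6 ± 45.6 and 94.3 ± 15.4, Cd274 25.3 ± 9.81, 120 ± 23.8, 130 ± 0.996 and 137 ± 66.7 and Pdcd1lg2 0.515 ± 0.220, 19.5 ± 0.0779, 21.9 ± 5.65 and 38.4 ± 20.6. Their receptor chains gave Il2ra 0.515 ± 0.220, 2.29 ± 0.587, 13.4 ± 0.587 and 3.35 ± 2.75, Il2rb 0 ± 0, 25.9 ± 17.5, 61.2 ± 18.6 and 88.1 ± 10.3 and Il2rg 104 ± 2.05, 440 ± 106, 355 ± 57.3 and 347 ± 50.7. Spleen CD8 T cells gave Pdcd1 4.80 ± 2.42, 9.49 ± 6.87, 9.27 ± 9.67 and 7.29 ± 2.04, Cd274 11.0 ± 1.42, 14.3 ± 1.75, 9.45 ± 0.298 and 7.94 ± 2.96 and Pdcd1lg2 5.97 ± 3.02, 5.45 ± 5.52, 3.48 ± 0.359 and 4.24 ± 0.505. Receptor chains of spleen CD8 T cells were Il2ra 6.54 ± 0.0346, 7.39 ± 7.18, 3.20 ± 1.55 and 1.60 ± 0.486, Il2rb 326 ± 59.4, 258 ± 26.3, 493 ± 124 and 573 ± 3.57 and Il2rg 498 ± 166, 514 ± 37.7, 530 ± 25.3 and 413 ± 31.9. In PD1-IL2v against control, all 6 passed the edgeR test in tumor CD8 cells and in macrophages, and no target in spleen CD8 T cells. In tumor CD8 cells calls ended for Pdcd1 (edgeR adjusted p = 0.0527) without PD1-IL2v tumor 2, Pdcd1lg2 (edgeR adjusted p = 0.241) without control tumor 1, and with a CD3 UMI for Il2ra (edgeR adjusted p = 0.0669), Pdcd1lg2 (edgeR adjusted p = 0.608) and Il2rg (0.55 ± 0.23). In macrophages calls ended for Il2ra (edgeR adjusted p = 0.0510 to 0.0904) without either PD1-IL2v or control tumor. Pdcd1 and Il2rb in macrophages moved with the T cell markers given above.

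CD8 T cells made up 15.2% ± 0.208 of annotated cells in control, 12.8% ± 2.42 in aPD-L1, 33.9% ± 8.79 in PD1-IL2v and 31.3% ± 1.44 in combination spleens. B cells made up 51.6% ± 1.23 in control, 51.3% ± 5.18 in aPD-L1, 29.2% ± 1.41 in PD1-IL2v and 28.3% ± 0.124 in combination spleens. Gamma-delta T cells made up 0.0616% ± 0.0267 in control, 0.103% ± 0.0589 in aPD-L1, 1.5% ± 0.0955 in PD1-IL2v and 1.77% ± 0.0749 in combination spleens. Monocytes made up 5.60% ± 2.0 in control, 4.92% ± 1.38 in aPD-L1, 1.54% ± 0.536 in PD1-IL2v and 3.14% ± 0.632 in combination spleens. In spleens of PD1-IL2v mice edgeR called CD8 T cells (log2 1.16 ± 0.34, adjusted p = 0.0381) and gamma-delta T cells (log2 4.46 ± 0.50, adjusted p = 2.1e-04) higher and monocytes (log2 -1.89 ± 0.46, adjusted p = 0.0198) lower than in control spleens. The CD8 call was lost at log2 0.86 to 1.17 without either combination or control spleen or PD1-IL2v spleen 2 and the monocyte call at log2 -1.55 to -1.47 without PD1-IL2v spleen 2 or control spleen 1. Among T and NK cells alone the CD8 change was 0.31 and its call ended. In combination spleens gamma-delta T cells were higher (log2 4.71 ± 0.50, adjusted p = 1.3e-04) by edgeR. The count of 1 class became 3 without PD1-IL2v spleen 1 or 2 or aPD-L1 spleen 1 or 2. aPD-L1 against control, combination against PD1-IL2v and the interaction had 0 edgeR calls, with 0, 0 and 0 classes at an unadjusted p under 0.05. The exact permutation test over 4 against 4 libraries gave 0.0286 (adjusted 0.0686) for CD8, B, NK and gamma-delta T cells and monocytes.

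In spleen CD8 T cells PD1-IL2v against control raised the immediate-early gene Fos (5.42 ± 0.32), the MAP kinase phosphatase Dusp1 (5.39 ± 0.23) and Jun (4.72 ± 0.27). It lowered the IGF-binding protein gene Igfbp4 (-4.52 ± 0.23), Tuba1b (-2.14 ± 0.27) and Rgcc (-2.10 ± 0.30). Called list members included Ifng (4.64 ± 0.26), Ccl3 (3.22 ± 0.33), Gzmb (3.88 ± 0.36), Nr4a2 (3.38 ± 0.30), Nr4a1 (3.55 ± 0.38) and Cd160 (1.22 ± 0.21). Of 18 stress and immediate-early genes, 12 rose (13 higher and 1 lower adjusted over the list alone; median log2 1.74). By camera these 18 were higher (adjusted p = 2.1e-14, adjusted p = 0.275 with an estimated correlation). Of 18 effector and cytotoxic genes, 9 rose (10 higher adjusted over the list alone; median log2 0.72, 1 background gene). Camera on these 18 was higher (adjusted p = 5.2e-07, adjusted p = 0.426 with an estimated correlation). Of 20 IFN-gamma response genes, 1 rose and 6 fell (1 higher and 8 lower adjusted over the list alone; median log2 -0.33). These 20 were lower by camera (adjusted p = 0.00783, adjusted p = 0.448 with an estimated correlation). Of 8 NK cell marker genes, 3 rose (4 higher adjusted over the list alone; median log2 0.88, 3 background genes). By camera these 8 were higher (adjusted p = 0.0118, adjusted p = 0.448 with an estimated correlation). EdgeR called 666 of 9580 genes (425 higher, 241 lower), the named genes at an adjusted p of at most 0.00249. The count of 666 became 184 without PD1-IL2v spleen 2 and 1455 without control spleen 2. Calls were lost for Cd160 (log2 0.95) without PD1-IL2v spleen 2. Fos (ENSMUSG00000021250) lies at 85473890 to 85477273 on chromosome 12 (plus strand) in GRCm38.

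**Figure D3:**
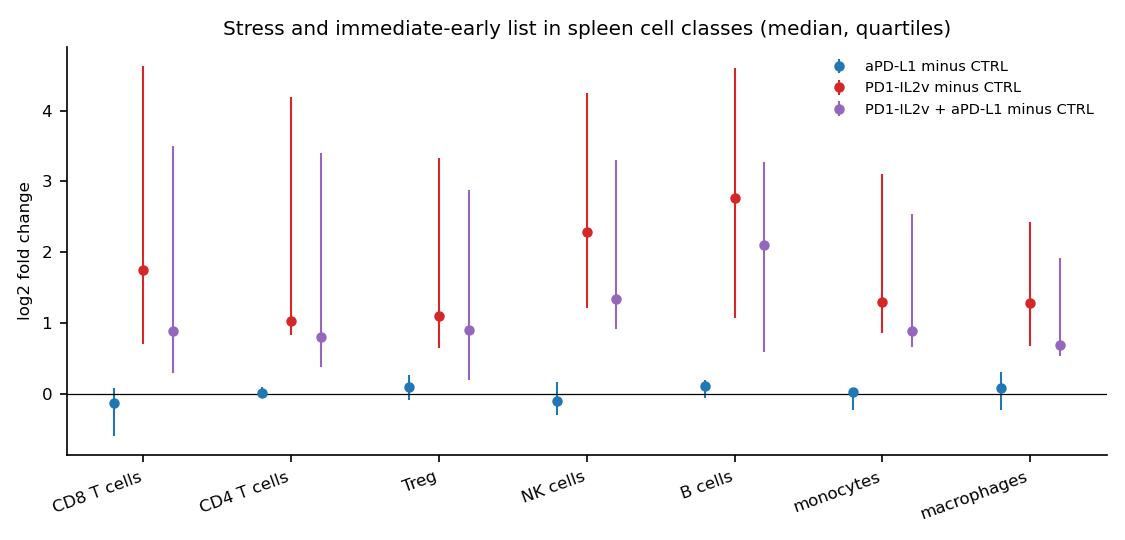
Median log2 fold change (y axis, points) and quartiles (bars) of the stress and immediate-early list in 7 spleen cell classes (x axis) for 3 contrasts against control. Medians for PD1-IL2v were 2.77 in B cells and 1.74 in CD8 T cells.

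Spleen CD4 T cells of PD1-IL2v mice had higher Fos (5.77 ± 0.35), the G protein signalling regulator Rgs1 (5.63 ± 0.56) and Jun (5.28 ± 0.30) and lower Ddit4 (-2.47 ± 0.44), AI467606 (-2.21 ± 0.31) and Ly6c1 (-2.04 ± 0.31) than control. Of 14 stress and immediate-early genes, 10 rose (14 higher adjusted over the list alone; median log2 1.02). Camera on these 14 was higher (adjusted p = 1.7e-18, adjusted p = 0.0406 with an estimated correlation). Of 6 exhaustion genes, 5 rose (5 higher adjusted over the list alone; median log2 3.75). These 6 were higher by camera (adjusted p = 5.2e-09, adjusted p = 0.0406 with an estimated correlation). Independence from the immediate-early rise was not tested. Of 6 neutrophil marker genes, 3 rose (6 higher adjusted over the list alone; median log2 4.17, 6 background genes). By camera these 6 were higher (adjusted p = 1.2e-09, adjusted p = 0.133 with an estimated correlation). EdgeR called 215 of 5715 genes (186 higher, 29 lower; DESeq2 108). The count of 215 became 99 without PD1-IL2v spleen 2 and 91 with equal cell numbers. Calls ended for Ddit4 (log2 -2.48) without either combination spleen. Spleen NK cells had higher Dusp1 (3.04 ± 0.296 in control and 471 ± 245 CPM in PD1-IL2v), Rgs1 (6.87 ± 0.27) and Fos (3.04 ± 0.296 in control and 273 ± 77.6 CPM in PD1-IL2v) and lower Kcnj8 (77.7 ± 41.8 in control and 3.61 ± 3.49 CPM in PD1-IL2v), Cox6a2 (-3.57 ± 0.56) and the stem cell factor receptor Kit (-2.57 ± 0.56). Of 14 stress and immediate-early genes, 11 rose (12 higher adjusted over the list alone; median log2 2.28). Camera on these 14 was higher (adjusted p = 4.4e-18, adjusted p = 0.0759 with an estimated correlation). EdgeR called 262 of 5062 NK genes (183 higher, 79 lower; DESeq2 101). The count of 262 became 127 without PD1-IL2v spleen 2 and 82 with equal cell numbers.

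In combination against control spleens, again across batches, CD8 T cells had higher Fos (4.91 ± 0.32) and Dusp1 (4.65 ± 0.23). Igfbp4 (-5.54 ± 0.26) and Rgcc (-2.54 ± 0.31) were lower there. EdgeR called 566 CD8 genes (379 higher, 187 lower), 352 CD4 genes (262 higher, 90 lower) and 196 NK genes (145 higher, 51 lower). The count of 566 became 166 without combination spleen 1, 172 without combination spleen 2 and 1518 without control spleen 1. The CD4 count became 189 without combination spleen 1, 94 without combination spleen 2, 728 without control spleen 1 and 196 with equal cell numbers, and the NK count 324 without PD1-IL2v spleen 1, 306 without PD1-IL2v spleen 2, 100 without combination spleen 1, 322 without control spleen 1 and 79 with equal cell numbers.

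aPD-L1 against control gave 0 edgeR calls in spleen CD8 T cells (169 at an unadjusted p under 0.05, 0 by DESeq2) and 0 in CD4 T cells (64 unadjusted, 0 by DESeq2). The genes named for the following small counts were chosen after their values were seen. Spleen NK cells had Lars2 (1.22) (113 unadjusted). Combination against PD1-IL2v gave Igkv16-104 (7.13, background), Igkv4-57 (4.47, background), Igkv6-15 (-3.38, background), Ifng (-1.22), Ighv12-3 (-7.86, background) and Ighv6-3 (-4.69, background) in CD8 T cells, Igkv6-15 (-8.29, background), Igkc (2.17, background), Lyz2 (1.60, background) and Ighm (1.36, background) in CD4 T cells and Ighm (1.5, background) in NK cells, by edgeR. The interaction gave 0 edgeR calls in CD8 T cells (361 unadjusted, 0 by DESeq2), Igkc (2.10, background), Lyz2 (2.60, background) and Ighm (1.54, background) in CD4 T cells and Igkv1-117 (5.80, background) in NK cells. Counts without single spleens (group and number) moved. CD8 T cells under aPD-L1 had 1 without either PD1-IL2v and 12 without control 2. CD8 T cells between combination and PD1-IL2v had 3 without PD1-IL2v 2, 62 without control 1 and 63 without control 2. CD8 T cells in the interaction had 1 without combination 2 and 300 without control 2. CD4 T cells under aPD-L1 had 3 without PD1-IL2v 1 or aPD-L1 2 or control 1, 1 without PD1-IL2v 2, 2 without aPD-L1 1 and 5 without control 2. CD4 T cells between combination and PD1-IL2v had 8 without PD1-IL2v 1, 18 without PD1-IL2v 2 or control 2, 2 without combination 1 and 16 without control 1. CD4 T cells in the interaction had 18 without PD1-IL2v 2, 0 without combination 1 or aPD-L1 2, 5 without aPD-L1 1 and 46 without control 2. NK cells under aPD-L1 had 3 without either PD1-IL2v or combination 2, 2 without combination 1 and 0 without aPD-L1 1. NK cells between combination and PD1-IL2v had 6 without PD1-IL2v 1, 39 without PD1-IL2v 2, 0 without combination 1, 3 without combination 2, 5 without aPD-L1 1, 4 without aPD-L1 2, 18 without control 1 and 20 without control 2. NK cells in the interaction had 7 without PD1-IL2v 1, 19 without PD1-IL2v 2, 0 without combination 1, 3 without combination 2 or aPD-L1 1 and 36 without control 2.

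Clonal expansion of tumor T cells was compared as the share of TCR cells in clones of 2 or more, after drawing 34 cells per library. It averaged 23.6% ± 20.7 in control, 21.3% ± 5.26 in aPD-L1, 38.5% ± 2.51 in PD1-IL2v and 40.8% ± 12.7 in combination tumors. Libraries given PD1-IL2v averaged 39.7% and the others 22.4%, a difference of 17.2 percentage points that did not pass the exact two-sided permutation test over 4 against 4 libraries (p = 0.0857). The share in the largest clone differed by -0.577 percentage points (exact permutation p = 0.914). Undrawn shares differed by 48.1 points (exact permutation p = 0.0286), with 34 to 1937 TCR cells per library. With Cell Ranger clonotypes the drawn difference was 25.2 points (exact permutation p = 0.0286), and for clones of 3 or more cells 9.06 (exact permutation p = 0.257). In CD8 T cells alone it was 0.828 (exact permutation p = 0.971), over 7 libraries drawn to 23 cells because control tumor 1 had too few. Without control tumor 1 alone it was 12.7 (exact permutation p = 0.171), and without control tumor 2 alone, drawn to 68 cells, 28.2 (exact permutation p = 0.0286). Of the control tumors' TCR cells, 69.1% and 70.6% shared barcode and CDR3 sequences with another library, against 0.236% to 1.83% elsewhere. Control tumor 1 shared 24 such cells with control tumor 2, so these 2 are not independent, and 20 with combination tumor 2. Control shares may thus include cells of other libraries. Without such cells, a step chosen after seeing the data, the difference was 19.8 (exact permutation p = 0.0286). That left 7 libraries drawn to 21 cells, control tumor 2 having too few.

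**Figure D4:**
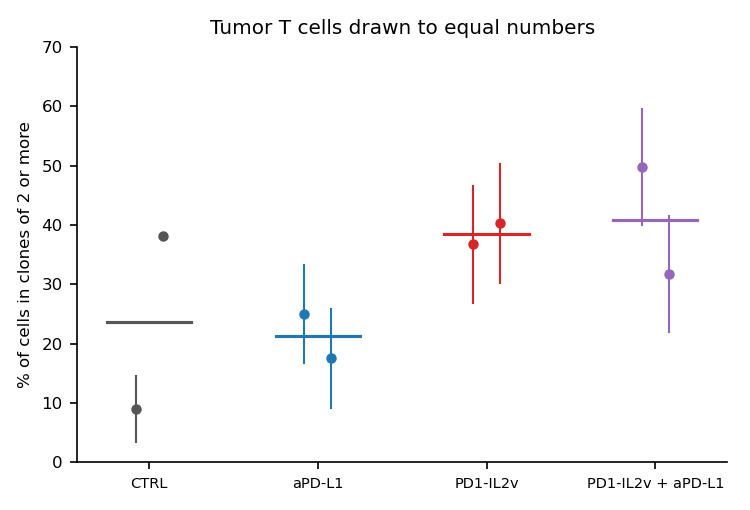
Share of TCR cells in clones of 2 or more (y axis, %) after drawing 34 cells, with 1 point per tumor library, bars of 1 SD over 1000 draws and lines at group means. The smallest library, control tumor 2, was used whole and has no bar. Group means were 23.6% in control and 38.5% in PD1-IL2v tumors.

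Lists not given above follow for 1 class and contrast each. In spleen CD8 T cells, PD1-IL2v minus control, of 9 B cell marker genes, 0 passed the edgeR test (0 higher adjusted over the list alone; median log2 -0.39, 9 background genes). The set leaned lower without passing camera (adjusted p = 0.226, adjusted p = 0.783 with an estimated correlation). In tumor CD8 T cells, PD1-IL2v minus control, of 5 fibroblast and pericyte marker genes, 4 fell (4 lower adjusted over the list alone; median log2 -6.42, 5 background genes). By camera these 5 were lower (adjusted p = 0.00277, adjusted p = 0.220 with an estimated correlation). The islet hormone and the erythroid and platelet marker lists had fewer than 5 measured members in every class and were not set-tested.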

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

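The tests of action on T and NK cells, handling, cancer cells under the CD8 label, free RNA, doublets and T cell RNA as a source of interferon genes were chosen after the results were seen; those of depth and of resting T cells were fixed before the thinned shares were seen, and that of T cell RNA in B cells before its value but after the CD3 shares and stress medians of B cells were.

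The interaction test in edgeR called 301 genes of tumor macrophages, 2 of tumor CD8 T cells, 3 of spleen CD4 T cells and 1 of spleen NK cells. It called the shares of 3 tumor classes, and single libraries ended each call. Among immune cells alone 0 classes were called, but fibroblasts were not among the classes tested there. The ceiling on shares leaves the CD8 and CD4 terms undecided. Background genes were 1 of the tumor CD8, 3 of the spleen CD4 and 1 of the NK genes, and without background genes these counts were 0. In macrophages 37 of the 165 lower and 0 of the 136 higher genes were background, and 279 were called without background genes. In CD8 T cells 334 of 9374 genes were called in both tissues (PD1-IL2v against control), and 32 of them had opposite signs with separated libraries and were not background genes; the difference was not tested.

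Stress and immediate-early genes were higher in spleen cells of mice given PD1-IL2v, the lower of the 2 medians in B cells being 2.10, and medians in tumor CD8, cancer and B cells and macrophages ran from 0.53 to 1.49 (0 B cell genes called), against -0.13 to 0.81, highest in cancer cells, under aPD-L1 alone within batch 2. With a CD3 UMI in 21.4% to 54.6% of these spleens' B cells (13.7% and 16.2% in control), T cell RNA was put at 13.0% to 36.3% of B cell RNA. It would make up a median of 0.0441 to 0.173 of the CPM of the 8 stress genes called in B cells of both groups. Single genes reached 0.606, and NK RNA a median of at most 0.122. For these genes, picked by their rise, this argues against T cell RNA as the main source. But the highest median lay under its bound by less than the spread between spleens, so a part may be T cell RNA. The lowest median over CD8, CD4, NK and B cells and monocytes was 0.795, as handling or sequencing batch would give. Batch and PD1-IL2v cannot be told apart here, so handling may account for the rise. Action on T and NK cells alone, with a response passed between cell types, stays open and untested.

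In control tumors 16.7% and 49.1% of CD8-labelled cells had a CD3 UMI, against 83.8% and 91.9% in aPD-L1 tumors. Thinned to 1000 UMIs, which left out 52 of 132 and 18 of 57 control and 55 of 339 and 38 of 457 aPD-L1 cells, the shares were 27.5% and 69.2% against 88.4% and 93.6%, the nearest libraries lying 19.1 percentage points apart, between the bounds set for and against depth. Control spleens (81 of 1126 and 25 of 721 cells left out) lay at least 19.1 points above the highest control tumor, also between the bounds for resting T cells with little CD3 RNA. Cancer marker CPM in the CD8-labelled control cells without CD3 was at least 0.536 of that in cancer-labelled cells of the same tumor, consistent with cancer cells or their RNA under the CD8 label. Contrasts of tumor CD8 cells against control may therefore compare different cell types.

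T cell transcripts appeared in cancer-labelled cells of tumors given PD1-IL2v. Cells without a CD3 UMI exceeded the share of a single free RNA rate by at least 18.1 percentage points in each of 4 tumors, which argues against free RNA alone. Cells with a CD3 UMI had a TCR more often by at least 34.3 percentage points, as droplets holding a T cell and a cancer cell would, but their median UMIs were lower than in cells without in 3 of 4 tumors (8216 against 9683, 13911 against 14812, 10496 against 12035, but 10799 against 5874 in combination tumor 2), where such droplets would add UMIs, so doublets stay open. Among cancer-labelled cells without CD3, 5 IFN-gamma list genes were called higher, exactly the least number set against T cell RNA as their source. That bound leaves a part from T cell RNA possible.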

How the results depend on the processing

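The selections of cells by CD3 UMI or label (each also with an estimated correlation), shared TCR cells left out, and PD1-IL2v against aPD-L1 were chosen after seeing the data. Of 125 named gene results, 85 stayed past the threshold with each library left out, 44 lost the call in at least 1 other setting, and no named gene reversed. Of 49 list calls at the preset correlation, the estimated correlation ended 47, all but exhaustion and stress genes of spleen CD4 T cells in PD1-IL2v against control, and fry ended 16. Of 32 list calls tested in a selection of cells, 3 ended and 1 reversed. Of 237 gene counts in other settings, 102 moved by over 1.5 times. The cause was not tested unless stated. A lone library of a group was assumed to vary like the other groups. Tumor CD4 contrasts with control could not be fitted, since control tumors held under 10 such cells.

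With equal cell numbers, which leaves fewer cells, the counts were, for PD1-IL2v against control, tumor CD8 501, tumor macrophages 646, spleen CD4 91, spleen NK 82. Tumor CD8 44, tumor macrophages 137, spleen CD4 1, spleen NK 0 came from aPD-L1 against control. Tumor CD8 434, tumor macrophages 397, spleen CD4 196, spleen NK 79 came from the combination against control. Tumor CD8 0, tumor CD4 1, tumor macrophages 1, spleen CD8 2, spleen NK 4 came from the combination against PD1-IL2v. Tumor CD8 0, tumor macrophages 65, spleen NK 2 came from the interaction. Tumor CD8 132, tumor CD4 322 came from PD1-IL2v against aPD-L1. Without background genes, which removes tested genes, tumor CD8 had 1836 for PD1-IL2v, 82 for aPD-L1 and 1698 for the combination against control. Cancer cells had 221 for PD1-IL2v and 512 for the combination. Tumor CD8, spleen CD4 and spleen NK had 0 in the interaction, and spleen CD8, CD4 and NK 0 for combination against PD1-IL2v. In CD3-positive CD8-labelled tumor cells the counts were 437 for PD1-IL2v, 8 for aPD-L1 and 314 for the combination against control, and 0 in the interaction. Without the low-count filter, which tests more genes, the counts were, for aPD-L1 against control, tumor CD8 1693, tumor macrophages 1181, tumor endothelial 172, tumor cancer 704, spleen CD8 6, spleen CD4 4, spleen NK 4. Tumor CD8 8, tumor CD4 34, tumor macrophages 80, tumor cancer 180, spleen CD8 61, spleen CD4 21, spleen NK 24 came from the combination against PD1-IL2v. Tumor CD8 401, tumor macrophages 797, tumor cancer 368, spleen CD8 16, spleen CD4 9, spleen NK 8 came from the interaction. Against control, tumor cancer and spleen CD8 had 1733 and 1047 for PD1-IL2v and 2293 and 956 for the combination. With both control tumors summed as 1 sample the counts were, for aPD-L1 against control, tumor CD8 2190, tumor macrophages 379, tumor endothelial 89, tumor cancer 0. Tumor CD8 had 3 for combination against PD1-IL2v, 1001 for the interaction and 2792 for PD1-IL2v against aPD-L1. Tumor macrophages had 698 for combination against control. With DESeq2 the counts were, for combination against PD1-IL2v, tumor CD8 5, tumor CD4 0, tumor macrophages 18, tumor cancer 7, spleen CD4 2. Tumor CD8 250, tumor cancer 81, spleen NK 0 came from the interaction. Tumor CD4 290 came from PD1-IL2v against aPD-L1. Tumor endothelial 52, tumor cancer 256 came from aPD-L1 against control. Against control, spleen CD8, CD4 and NK had 370, 137 and 85 for the combination, and CD4 and NK 108 and 101 for PD1-IL2v. With RLE scaling tumor CD8 had 1 in the interaction and spleen NK 2 for combination against PD1-IL2v. In cancer cells without a CD3 UMI the counts were 56 for PD1-IL2v, 37 for aPD-L1 and 111 for the combination against control. Among immune cells alone 5 tumor classes were called for PD1-IL2v and 5 for the combination against control, and 0 in the interaction. Among T and NK cells alone 1 spleen class was called for PD1-IL2v against control.

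The TCR difference passed the exact permutation threshold with Cell Ranger clonotypes (25.2), undrawn (48.1) and without shared cells and control tumor 2 (19.8). It did not for clones of 3 or more cells (9.06) or in CD8 T cells without control tumor 1 (0.828). Reversed results were the combination share of macrophages under TMM (0.350), that of NK cells among immune cells (-0.0153), and, in cancer cells without a CD3 UMI, the proliferation (camera adjusted p = 1.7e-06, adjusted p = 0.365 with an estimated correlation) and beta cell identity (camera adjusted p = 0.0451, adjusted p = 0.253 with an estimated correlation) lists.

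Leaving out 1 library at a time gave these ranges. For PD1-IL2v against control, tumor CD8 916 to 4656, tumor macrophages 773 to 1493, tumor cancer 543 to 1054, spleen CD8 184 to 1455, spleen CD4 99 to 289, spleen NK 127 to 345, tumor cell classes 7 to 8, spleen cell classes 1 to 4. For aPD-L1 against control, tumor CD8 26 to 2781, tumor macrophages 302 to 674, tumor endothelial 18 to 110, tumor cancer 0 to 170, spleen CD8 0 to 12, spleen CD4 0 to 5, spleen NK 0 to 3, tumor cell classes 6 to 7, spleen cell classes 0 to 0. For combination against control, tumor CD8 757 to 4479, tumor macrophages 516 to 1181, tumor cancer 608 to 1461, spleen CD8 166 to 1518, spleen CD4 94 to 728, spleen NK 100 to 324, tumor cell classes 7 to 8, spleen cell classes 1 to 3. For combination against PD1-IL2v, tumor CD8 0 to 3, tumor CD4 5 to 91, tumor macrophages 0 to 4, tumor cancer 0 to 1, spleen CD8 3 to 63, spleen CD4 2 to 18, spleen NK 0 to 39, tumor cell classes 0 to 0, spleen cell classes 0 to 0. For interaction, tumor CD8 1 to 1673, tumor macrophages 159 to 272, tumor cancer 0 to 2, spleen CD8 0 to 300, spleen CD4 0 to 46, spleen NK 0 to 36, tumor cell classes 0 to 4, spleen cell classes 0 to 0. For PD1-IL2v against aPD-L1, tumor CD8 187 to 2770, tumor CD4 274 to 977. The TCR difference ranged from 12.7 to 28.2.

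The labels do not show that replicate numbers pair animals across groups. Correlations of same-numbered libraries ran from -0.295 to 0.178. With the replicate block the counts were, for aPD-L1 against control, tumor CD8 502, tumor endothelial 50, tumor cancer 46, spleen CD4 2, spleen NK 2. Tumor CD8 3, tumor CD4 11, tumor macrophages 7, spleen NK 2 came from the combination against PD1-IL2v. Tumor CD8 6, spleen CD4 5, spleen NK 0, tumor cell classes 1 came from the interaction.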

Other observations

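The genes named here were chosen after the results were seen. Of the 32 genes with opposite signs in tumor and spleen CD8 T cells (PD1-IL2v against control), 14 were higher in the tumor. Log2 changes in tumor and spleen were 1.81 and -1.41 for Aim2, -1.37 and 3.18 for Ube2c and -1.50 and 2.74 for Klf4. The tumor values rest on control cells of which many lacked a CD3 UMI.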
